A study of Glycine max with 5 samples.

How the data were processed

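RNA from soybean (Glycine max, genotype Bragg) seedlings was measured on an Affymetrix soybean array in 5 samples. Per the labels' protocols, plants were grown for 10 days at 28 °C in potting mix under natural long days, root tips of 0.5 mm were dissected under a microscope and frozen in liquid nitrogen, and biotin-labelled cRNA was made from 6 µg of total RNA. The groups were taken from the sample titles: 3 root meristem arrays and 2 arrays of non-meristematic tissue. One label field calls the non-meristematic tissue leaf, while the protocol speaks of the remaining parts of the plant, so its exact makeup is open. The free-text descriptions of all 5 samples speak of early embryo stages, which goes with none of their other label fields; they were not used, and the identity of the samples rests on the titles and tissue fields. The titles call the samples biological replicates and give no further detail, so p-values measure the spread between these samples.

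The deposited values were MAS5 signal intensities on a linear scale, per the submitters' processing notes. MAS5 is the Affymetrix method that condenses the probe pairs of a probe set into 1 signal. Its version, scaling target and detection calls are not given in the sources used here. The 2% trimmed mean signal lay between 268 and 277 on the 5 arrays, and the median between 77.8 and 111.6. The table held 37593 probe sets, of which 14928 had the prefix Gma and 22665 the prefix GmaAffx. Control probe sets and probe sets for other organisms, for which a background level and a check of RNA quality had been planned, were not analysed here. The planned substitute was used: background was the 25th percentile of each array, 17.9 to 37 signal units, and a probe set was tested when it lay above background on at least 2 arrays. It was 17.9 to 22.5 on the root meristem arrays, and 37 and 26.3 on non-meristematic arrays 1 and 2. Arrays carry no count of molecules, and the number of arrays limits the precision.

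Signals below 0.1 were set to 0.1 and log2 was taken, with no further scaling between arrays. Differences between the groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and p-values were adjusted by Benjamini-Hochberg over all probe sets tested. A probe set passed at an adjusted p below 0.05 together with an absolute log2 difference of at least 1. The fit had 3 residual degrees of freedom per probe set and borrowed 3.68 more from the other probe sets. Fold values are 2 raised to the log2 difference, with its standard error (SE) from limma. Where every array of one group lay at or below background, the fold is given as "at least", with the dim group set, array by array, to the higher of background and its own signal.

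Gene names came from the platform annotation, updated through Entrez numbers with a RefSeq gene table of the assembly Glycine_max_v4.0, which served for names only. Of the 37593 probe sets, 8677 had 1 gene, 370 had several genes and 28546 were not listed, so that most probe sets are unnamed here. Of the 8677 probe sets, 8652 matched by Entrez number. They stood for 6029 genes, of which 1129 had a symbol or synonym other than a LOC number. Product descriptions were not used here, so gene lists were filled by symbol and synonym alone. Of 43 lists fixed before the data were examined, 29 had at least 1 member. A further 22 lists were drawn up from the gene symbols on the array after the files were opened and before any difference was computed. Each gene was represented by its probe set with the highest mean log2 signal among those tested.

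Lists with at least 5 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over 15 lists fixed beforehand and, separately, over 20 lists drawn from symbols. Camera with an estimated correlation and fry were run beside it. Named genes followed a rule fixed beforehand. It took the 8 probe sets in each direction with the largest log2 difference among those above background on all 5 arrays with no overlap between the groups. It also took the 6 in each direction with the smallest adjusted p among those above background on every array of one group and on none of the other, and up to 4 members of each list described. The rule asked for a product description, and a name other than a LOC number was used in its place. It gave 45 probe sets, of which 26 were left without those whose suffix (_x_at or _s_at) marks them as able to cross-hybridize.

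The procedure was tested on simulated data for this comparison, with 200 of the 30941 probe sets changed by known amounts. It recovered 25% of the changes of log2 size 1.5 and 80% of those of log2 size 3, all in the right direction, with 7 false calls. A simulated list of 20 genes moved by 1.5 had a camera adjusted p of 3.38e-20 (0.0395 with an estimated correlation), and 0 of 20 unmoved lists passed. The simulated noise was independent between genes, whereas the correlation estimated in the data was 0.645 for seed maturation protein genes. The unmoved lists therefore cannot show how often camera at its preset correlation calls correlated lists. The simulation also changed far fewer probe sets than the 12348 past the adjusted p alone in the data. Its adjustment was stricter, so its recovery rates do not carry over. The alternatives tried were quantile normalization, median centring, 2 other treatments of low signals, other filters, other variance models, array weights, removal of probe sets marked as able to cross-hybridize (suffix _x_at or _s_at), the replicate number as a block, stricter thresholds, other list tests, and each array left out. Annotation and figures used Python 3.11.15.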

Results

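The transcripts of soybean root tips were compared with those of non-meristematic tissue of the same 10-day-old seedlings, with the stated purpose of finding genes enriched in the root meristem. The data were 3 arrays of root tips cut at 0.5 mm, labelled as root apical meristem, and 2 arrays of non-meristematic tissue, labelled as leaf in one field. Means below are MAS5 signals ± SD over n = 3 root meristem and n = 2 non-meristematic arrays, and folds are given with the log2 difference ± SE. The contrast sets a root tip against tissue that is described as leaf, so that differences between organs and differences between dividing and differentiated tissue cannot be separated in it.

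The root meristem arrays were close to each other and far from the non-meristematic arrays. Across the 30941 probe sets tested, Spearman correlations of log2 signal were 0.965 to 0.976 between root meristem arrays, 0.871 between the 2 non-meristematic arrays and 0.599 to 0.626 between the groups. These are correlations across probe sets, which are not independent replicates. The first principal component held 81.5% of the variance and the second 10.7%. Among probe sets above background on both arrays of a pair, 0.052% to 0.76% differed more than 4-fold between root meristem arrays, 3.39% between the non-meristematic arrays and 10.2% to 13% between the groups. The non-meristematic arrays thus had the wider spread, with the smaller number of arrays.

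Of the 30941 probe sets, 10060 differed at an adjusted p below 0.05 (limma) with a log2 difference of at least 1. Of these, 4452 were higher and 5608 lower in root meristem. At the adjusted p alone the count was 12348. Among those that differed, 776 were above background on all root meristem arrays and on neither non-meristematic array, and 1629 showed the opposite pattern. Each array was judged against its own background, so the groups were judged at different levels. These were 17.9 to 22.5 in root meristem, and 26.3 and 37 in non-meristematic tissue. The groups did not overlap at 19695 probe sets, against 20% expected by chance for 3 arrays against 2. At the level of named loci, 5650 genes were tested, of which 1053 were higher and 1187 lower. The split between directions depended on the scaling: it was 5719 higher and 4717 lower after quantile normalization, and 6574 higher and 4948 lower after median centring. These scalings moved the median log2 difference of all probe sets from 0.07 to 0.30 and 0.32. Testing against a log2 difference of 1 (limma treat) left 4032 probe sets, 1161 higher and 2871 lower.

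The largest increases in root meristem, among genes with a name other than a LOC number measured on all 5 arrays, included several enzymes of isoflavonoid synthesis. CHR1, a chalcone reductase, had a signal of 4869 ± 329 in root meristem and 72.5 ± 26 in non-meristematic tissue, a 69.4-fold difference (log2 6.12 ± 0.25, adjusted p = 3.34e-05). CHS8, a chalcone synthase, was 44.7-fold higher (2288 ± 476 against 51.7 ± 16.3, adjusted p = 7.17e-05). The isoflavone synthase genes IFS2 and IFS1, whose products make the isoflavone skeleton, were 34.6-fold and 27.8-fold higher, with 4487 ± 744 against 133 ± 48.8 and 4706 ± 207 against 174 ± 54.4. Both were measured only by a probe set marked as able to cross-hybridize, so their signals may be shared. The named CHR1 probe set was also marked, while an unmarked one of that gene had a log2 difference of 7.08. LOC547581 (GSTU21), a glutathione transferase, was 30.6-fold higher and LOX10, a lipoxygenase, 26.4-fold higher, the latter with a wide spread in root meristem (1625 ± 895). GS1alpha, a cytosolic glutamine synthetase that fixes ammonium into glutamine, was 25.5-fold higher (2856 ± 388 against 111 ± 0.35). ALDH3H1, an aldehyde dehydrogenase, was 28.6-fold higher on the probe set named by the rule, while another of its probe sets was lower (log2 -3.09 ± 0.47), with signal above background on 2 of 3 root meristem arrays.

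Other genes had signal in root meristem and none above background in non-meristematic tissue. That background (26.3 and 37) was higher than on the root meristem arrays (17.9 to 22.5). The PIN2A signals of 25.2 and 26.1 in non-meristematic tissue would lie above the root meristem levels. On non-meristematic array 1, so would those of ODC1 (25.3) and CHR5 (32). DAO was at least 311-fold higher (9707 ± 550 against 2.40 ± 0.85, adjusted p = 2.46e-05). BBI-2, a Bowman-Birk protease inhibitor, was at least 242-fold higher (7592 ± 904 against 4.60 ± 2.26) and the chalcone reductase gene CHR5 at least 233-fold higher (7256 ± 113 against 25.9 ± 8.70). CHR5 was measured only by a probe set marked as able to cross-hybridize, and the DAO value also came from a marked probe set. PIN2A, an auxin efflux carrier gene, was at least 64.9-fold higher (2041 ± 334 against 25.7 ± 0.64, adjusted p = 2.76e-05). LOC548088 (ODC1) was at least 61.9-fold higher and the MYB transcription factor gene MYB92 at least 32.2-fold higher; another MYB92 probe set did not pass (log2 0.48 ± 0.38).

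Among the likewise named genes measured on all 5 arrays, those with the largest decreases in root meristem included a storage protein and several proteins of photosynthesis. VSPA, a vegetative storage protein of soybean leaves, had a signal of 46.4 ± 13 in root meristem and 9517 ± 1556 in non-meristematic tissue, a 209-fold difference (log2 -7.71 ± 0.28, adjusted p = 2.76e-05). CAB3, a chlorophyll a/b-binding protein of the light-harvesting complex, was 185-fold lower (38.5 ± 16.6 against 6629 ± 1145), while 1 of its 4 tested probe sets did not pass (log2 0.28 ± 0.34). SBPRP, a proline-rich cell wall protein, was 128-fold lower, and PETC, the Rieske iron-sulfur protein of the photosynthetic electron transport chain, 61.9-fold lower (97.3 ± 11.4 against 6085 ± 1517). CHLH, a subunit of the magnesium chelatase of chlorophyll synthesis, was 68.8-fold lower, and MIPS4, an inositol phosphate synthase, 57.3-fold lower; both varied widely between the non-meristematic arrays (2668 ± 2563 and 3884 ± 3373). F3H, a flavanone 3-hydroxylase, was 58.9-fold lower on one probe set, while its brighter probe set did not pass (log2 -0.96 ± 0.42, adjusted p = 0.118). PSAD, a photosystem I subunit, was 92.9-fold lower on one probe set, while its brightest probe set had a log2 difference of 0.67 ± 0.13, under the minimum size. The named probe sets of VSPA, CAB3, PETC, F3H and MIPS4 were marked as able to cross-hybridize.

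A further set had signal in non-meristematic tissue and none above background in root meristem. PRP3, another proline-rich protein, was at least 433-fold lower in root meristem (10.7 ± 5.5 against 8951 ± 2416), and GER10 at least 368-fold lower (10.3 ± 5.1 against 7652 ± 2408). LOC732565 (SGT3) was at least 204-fold lower. The values of PRP3, SGT3 and CYP83E8 came from probe sets marked as able to cross-hybridize. RCAALPHA, a Rubisco activase, was at least 194-fold lower (9.33 ± 3.0 against 4105 ± 1666), the cytochrome P450 gene CYP83E8 at least 186-fold lower and LOC547576 (GSTU3), a glutathione transferase, at least 116-fold lower.

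**Figure D1:**
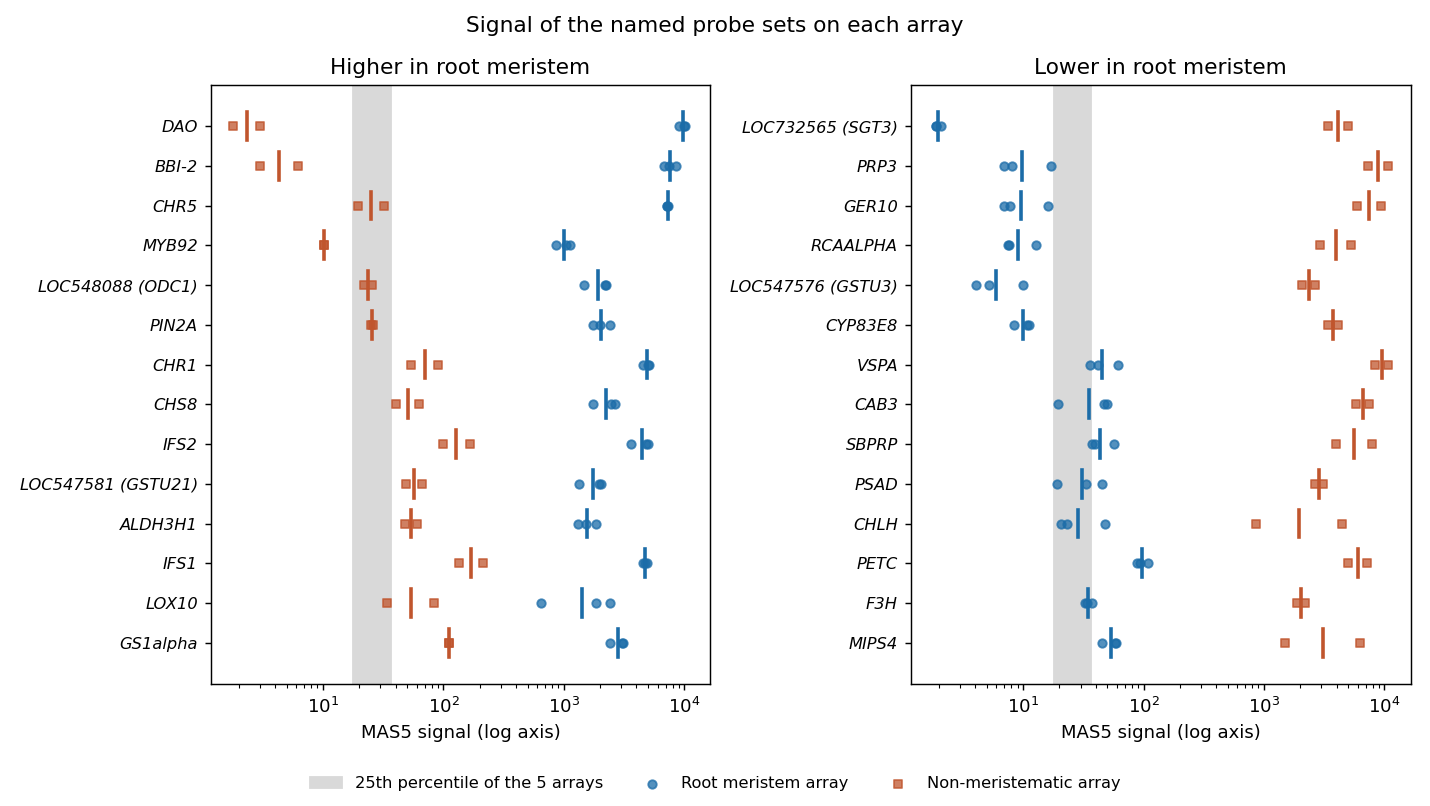
MAS5 signal (log axis) of probe sets of named genes, picked by the naming rule for the size or significance of their differences. Genes higher in root meristem are on the left and lower ones on the right. Each point is 1 array, and vertical bars are means of the log2 signals. The grey band spans the 25th percentiles of the 5 arrays, 17.9 to 37. The root meristem and non-meristematic arrays do not overlap in any row. The naming rule asked for this in genes above background on all 5 arrays, and in the others it nearly follows from the rule. DAO is the widest on the left, with 9707 ± 550 against 2.40 ± 0.85.

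The flavonoid and isoflavonoid list changed as a group, mostly upward in root meristem. Of its 20 measured genes, 13 were higher, 5 lower and 2 did not pass, with a median log2 difference of 2.15 (camera adjusted p = 0.0348; adjusted p = 0.807 with an estimated correlation). Adjusted over the list alone, 19 of the 20 genes had an adjusted p below 0.05, 14 higher and 5 lower. The higher genes included the chalcone reductase genes CHR1 and CHR5, the isoflavone synthase genes IFS1 and IFS2, CHS8 (25.2-fold on its brightest probe set, 5325 ± 371 against 219 ± 82.0), the chalcone isomerase gene CHI1A (log2 2.25 ± 0.20) and PAL2.1, a phenylalanine ammonia-lyase gene (log2 1.80 ± 0.24, with 2 other probe sets that did not pass). The chalcone reductase gene CHR4 did not pass (log2 0.97 ± 0.33, adjusted p = 0.0578). Those lower were FLS1, a flavonol synthase gene (at least 54.4-fold), ANS2, an anthocyanidin synthase gene (log2 -2.18 ± 0.35), CHI2-A, CHI3A1 and CHS1, the last on its probe set with the highest mean log2 signal (log2 -1.83 ± 0.49), while 4 other tested CHS1 probe sets, 3 of them above background on 1 of 2 non-meristematic arrays, had log2 differences of 1.30 to 1.85 and did not pass; the genes of this group outside the naming rule were chosen after their values were seen. One measured member, CHIA1, is a chitinase gene that matched by symbol (at least 11.5-fold higher), and without it the list's adjusted p was 0.0766. Its call was also lost after quantile normalization (adjusted p = 0.0546), median centring (0.108), with no filter (0.111) and without probe sets marked as able to cross-hybridize (0.684), which left 15 genes, 6 higher and 5 lower.

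Genes for vegetative storage proteins fell in root meristem. Of 5 measured members, 3 were lower and none higher, with a median log2 difference of -5.48 (camera adjusted p = 0.0261; adjusted p = 0.832 with an estimated correlation). With adjustment over the list alone and no minimum size, 4 had an adjusted p below 0.05, all of them lower. The vegetative lipoxygenase gene VLXC was lower (25.4 ± 4.2, above background on 2 of 3 root meristem arrays, against 4410 ± 1223), LOC547820 (VSP27) at least 499-fold lower and VSPA 44.5-fold lower on its brightest probe set (235 ± 47.8 against 10361 ± 1358). The VSP27 and VSPA probe sets used here were marked as able to cross-hybridize. This VSPA probe set also shares a design cluster number with H4 probe sets, so that its assignment is uncertain. The lipoxygenase genes VLXB and LOXB1 did not pass, with log2 differences of -0.70 ± 0.17 and 0.04 ± 0.17. The call was lost after quantile normalization (adjusted p = 0.0501) and without probe sets marked as able to cross-hybridize (0.152). With either non-meristematic array left out, fewer than 5 members passed the filter and the list could not be tested.

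Genes of photosynthesis and the chloroplast, in a list drawn from gene symbols, fell as a group. Of 21 measured genes 15 were lower and none higher, with a median log2 difference of -2.96 (camera adjusted p = 1.09e-06; adjusted p = 0.189 with an estimated correlation). CAB3 was 45.4-fold lower on its brightest probe set (189 ± 22.7 against 8688 ± 2096), PETC 61.9-fold lower and RCAALPHA at least 194-fold lower. ATPC, a subunit of the chloroplast ATP synthase, was also lower (18.4 ± 7.0, above background on 1 of 3 root meristem arrays, against 3922 ± 573). The 6 that did not pass included DGD2, a galactolipid synthase gene (log2 -0.19 ± 0.22), and PTOX, the plastid terminal oxidase gene (log2 0.27 ± 0.31). The smaller light-harvesting and photosystem list fixed beforehand had 2 members, CAB3, which was lower, and PSAD, which did not pass on its brightest probe set; adjusted over the list alone both had an adjusted p below 0.05, in opposite directions, with PSAD higher (log2 0.67).

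All 7 measured genes of the sieve element occlusion family, which encode structural proteins of phloem sieve elements, were lower in root meristem. Their median log2 difference was -2.85 (camera adjusted p = 0.0011; adjusted p = 0.368 with an estimated correlation; a list drawn from symbols). SEOA was 22.4-fold lower (73.4 ± 14.1 against 1623 ± 48.8, adjusted p = 8.31e-05), SEO-F3 14.9-fold lower (60.4 ± 10.1 against 904 ± 219), SEOF 13.6-fold lower and SEOC 5.19-fold lower.

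Genes named as seed maturation proteins, in a list drawn from symbols, were higher in root meristem as a group. Of 22 measured genes 15 were higher and none lower, with a median log2 difference of 3.12, or 2.74 with genes below background in one group held at their bound (camera adjusted p = 0.0011; adjusted p = 0.749 with an estimated correlation). PM30 was at least 131-fold higher (4457 ± 2220 against 1.45 ± 0.64, adjusted p = 3.48e-05; log2 1.04 ± 0.45 on another probe set, which did not pass), PM16 at least 40.4-fold (1479 ± 963 against 10.7 ± 6.9), PM29 at least 17.2-fold (670 ± 538 against 2 ± 0.28) and PGMPM19 15.0-fold (656 ± 166 against 43.7 ± 12.4). The root meristem arrays differed from each other in this list: its median signal was 413 on array 1, 217 on array 2 and 122 on array 3, against 28.6 and 14.8 on non-meristematic arrays 1 and 2, both below background. Without root meristem array 1 the count was 9 of 19 genes higher, and without array 2 it was also 9 of 19.

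**Figure D2:**
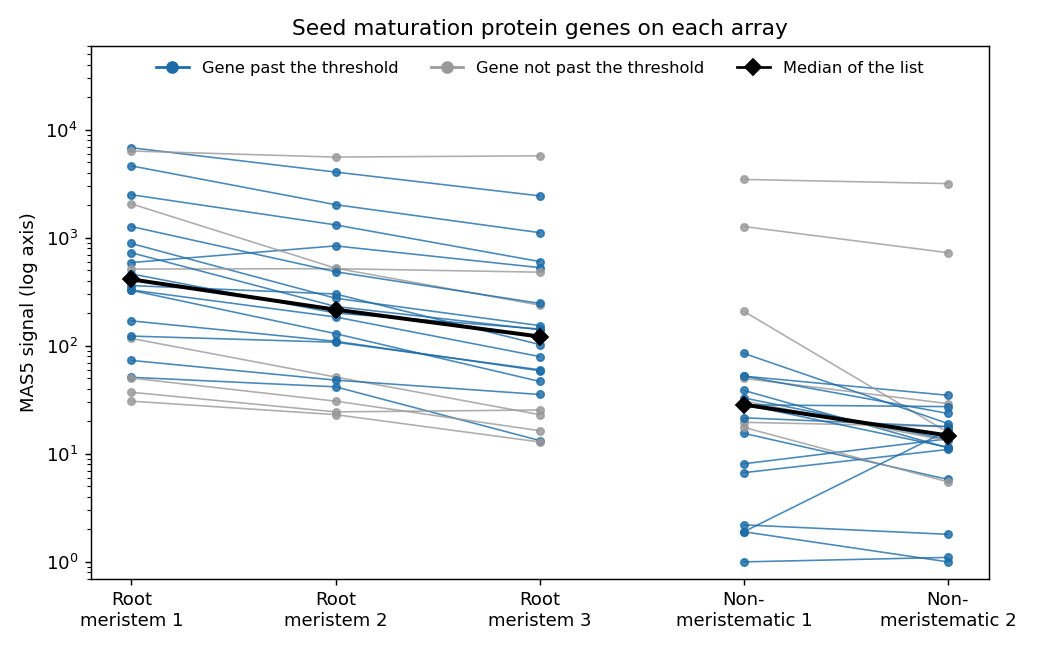
MAS5 signal (log axis) of the 22 seed maturation protein genes on each of the 5 arrays; thin lines join the values of a gene within a group, blue for the 15 that were higher in root meristem, and the black line is the median of the list. The median is 413, 217 and 122 on the root meristem arrays and 28.6 and 14.8 on the non-meristematic arrays.

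Genes of cell division and of auxin were few among the named probe sets. H4, a core histone gene, was 8.08-fold higher in root meristem (2105 ± 745 against 261 ± 115, adjusted p = 0.00196); its probe set shares a design cluster number with a VSPA probe set, so that its assignment is uncertain. LOC548079 (PCNA), the sliding clamp of DNA replication, was 2.09-fold higher (1891 ± 363 against 927 ± 341, adjusted p = 0.0228), a call that was lost under 7 alternatives: quantile normalization, a variance model without trend, the replicate block, and leaving out any 1 of the 3 root meristem arrays or non-meristematic array 2. In the auxin list, 1 of 5 genes was higher, 1 lower and 3 did not pass (camera adjusted p = 0.89). With adjustment over the list alone and no minimum size, 3 had an adjusted p below 0.05, 1 higher and 2 lower. PIN2A was the higher one, and AUX22, an auxin-responsive gene, was 15.5-fold lower (150 ± 24.0 against 2305 ± 174, adjusted p = 8.44e-05). ARF and AUX28 had log2 differences of -0.04 ± 0.18 and 0.07 ± 0.30. ARF was placed in the list by its symbol alone, so that its link to auxin is uncertain. The auxin list's median log2 difference was -0.04 and its mean 0.27, so that the 2 differ in sign. The 2 cytokinin genes on the array did not pass the filter, and cyclins, cyclin-dependent kinases and root meristem regulators were not analysed here because no symbol matched.

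**Figure D3:**
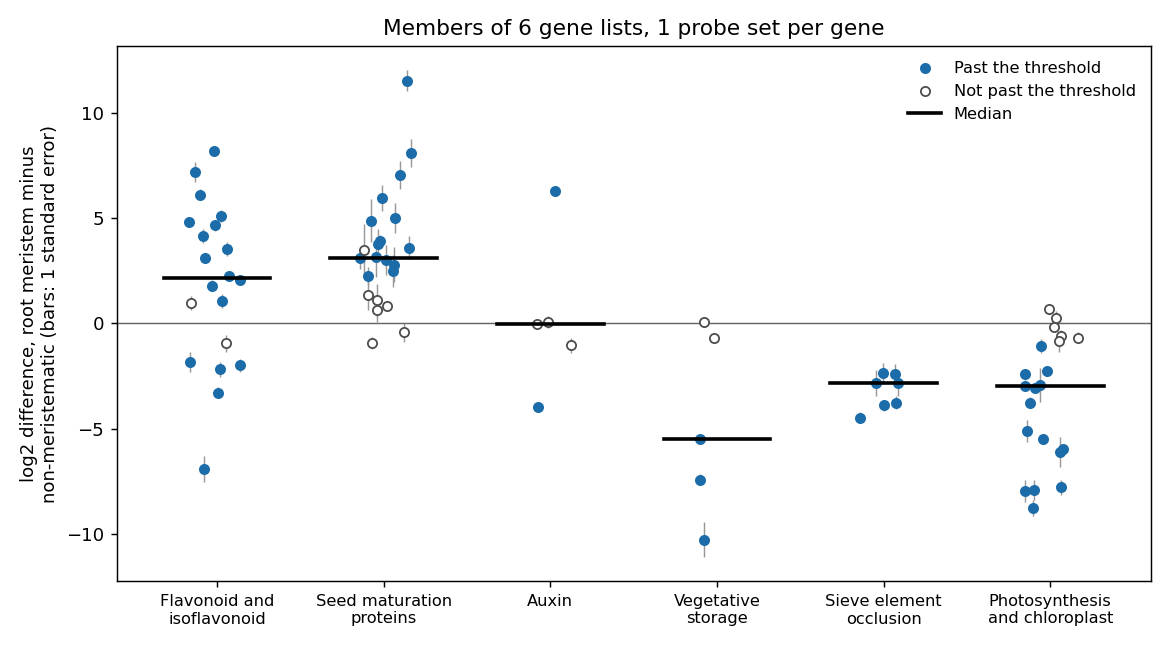
Log2 difference, root meristem minus non-meristematic, of each measured member of 6 gene lists, with 1 probe set per gene and bars of 1 SE; filled points passed the threshold and black lines are list medians. The medians run from 3.12 for seed maturation proteins to -5.48 for vegetative storage, and the auxin list lies around -0.04.

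Markers of tissues that the samples could hold moved in several directions. Of the leaf and shoot lists, both measured Rubisco activase genes of the carbon fixation list were lower in root meristem, and 2 of 4 shoot and leaf identity genes were lower with none higher. Of 22 genes fixed as markers of differentiated root, 2 were higher and 5 lower (camera adjusted p = 0.743; adjusted p = 0.998 with an estimated correlation). Of 5 class III peroxidase genes 1 was higher and 2 lower, and the 1 lignin gene measured was lower. Of 15 seed storage and late embryogenesis genes on the array 6 passed the filter, of which 4 were higher and none lower (camera adjusted p = 0.182). Of 8 storage protein genes, 0 lay above background on at least 2 root meristem arrays.

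Over all lists, 2 of 15 fixed beforehand and 3 of 20 drawn from symbols passed camera at its preset correlation. With an estimated correlation 0 of 15 and 0 of 20 passed, with 0 and 2 at an unadjusted p below 0.05. The estimate was -0.0127 for flavonoids and -0.0089 for photosynthesis, below the preset 0.01, and 0.0273 for sieve element occlusion. It was 0.258 for vegetative storage and 0.645 for seed maturation. A correlation above the preset therefore does not account for the lost calls of flavonoids and photosynthesis. With fry, which asks whether the genes of a list move on balance one way, 3 and 11 passed.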

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

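The filter at the array median, the flavonoid list without its chitinase genes and the array similarity under other settings were chosen after the data were seen. The counts of differing probe sets lay between 8020 and 11522 under the other scalings, filters and variance models and with any 1 array left out. Most of the 45 named probe sets were chosen for large or significant differences in the same data, which favours stability under other settings. Settings in which a probe set was not tested gave no value for it. Of 732 values for the 45 named probe sets under the alternatives, 725 kept their direction and side of the threshold, 7 (all of LOC548079, PCNA) no longer passed and 0 reversed. Of 118 list results 105 kept both, 12 no longer passed and 1 reversed. The levels above the 99th percentile of probe sets for other organisms, and the 90th percentile of soybean probe sets as a signal level, were not run.

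Stricter thresholds gave fewer probe sets: 4032 (1161 higher, 2871 lower) with limma treat and 6593 (2962 higher, 3631 lower) at an adjusted p below 0.01. Of the lists fixed beforehand, 0 passed camera after quantile normalization (flavonoid 0.0546, vegetative storage 0.0501), 1 after median centring (flavonoid 0.108), 1 with no filter (flavonoid 0.111), 0 without probe sets marked as able to cross-hybridize (flavonoid 0.684, vegetative storage 0.152) and 0 with an estimated correlation. The latter gave adjusted p-values of 0.807 for flavonoids, 0.832 for vegetative storage, 0.189 for photosynthesis, 0.749 for seed maturation and 0.368 for sieve element occlusion, so that 0 of the lists drawn from symbols passed; 11 of them passed with fry. The flavonoid list had 0.0766 without the chitinase genes. The auxin list pointed the other way with fry (adjusted p = 0.104), passing in neither test. Of the 45 named probe sets 26 were left without those marked as able to cross-hybridize, by construction. The mean Spearman correlation between the groups was 0.618 and became 0.732 with no filter. For the rest the cause was not tested.

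Leaving out 1 array gave 8032 to 10101 differing probe sets, and 1 or 2 lists fixed beforehand passed. With 1 non-meristematic array left out, 53.1% (without array 2) and 55.7% (without array 1) of the calls were higher in root meristem, against 44.3% with all arrays. A probe set seen only in the non-meristematic group cannot then pass a filter of 2 arrays, and the remaining array is assumed to vary like the others. Dim signals limit the folds of genes near background, and where every array of a group was at or below it a fold is only a bound.

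The replicate numbers 1 and 2 occur in both groups, and the deviations of same-numbered arrays did not go together (r = 0.012 across probe sets), so that the pairing rests on a number alone. With the replicate number as a block 7589 probe sets differed, and 8057 passed at the adjusted p alone, with 1 residual degree of freedom.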

Other observations

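The genes named in the first paragraph here were chosen after their values were seen, and so were the tests of seed tissue, of a single array and of general noise and all bounds in the last 2 paragraphs; the tests of dehydration genes and of the partner clock genes were set before their results were seen. Of 7 genes for seed-type protease inhibitors on the array, 4 passed the filter, and all 4 were higher in root meristem. The other genes, BBI, KTI1 and KTI3, lay above background on none of the 5 arrays. BBI-1 had 9145 against 56.3, with 1 of 2 non-meristematic arrays above background, and the Kunitz inhibitor genes KTI-2 and KTI-3 had log2 differences of 2.25 ± 0.12 and 2.54 ± 0.20. In the family of gibberellin-stimulated GASA peptides 9 of 15 genes were lower and 2 higher (camera adjusted p = 0.106; adjusted p = 0.749 with an estimated correlation), among them GASA22 (log2 -3.61 ± 0.55) and GASA21 (log2 1.84 ± 0.31). Of 6 SWEET sugar transporter genes 4 were lower and none higher (camera adjusted p = 0.23), among them SWEET31, at least 42.8-fold lower. Of 17 aquaporin genes 5 were lower and 1 higher (camera adjusted p = 0.16). The shoot and leaf identity genes LOC100500091 (YABBY11) and LOC100785458 (YABBY12) were at least 39.4-fold and 10.3-fold lower. Expansin and proline-rich protein genes went both ways: EXP1 (log2 3.53 ± 0.23) and PRP1 (2078 against 29.2, with 1 of 2 non-meristematic arrays above background) were higher, EXP4 (log2 -3.38 ± 0.71) was lower.

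Of 456 genes with at least 2 probe sets past the threshold, 7 had probe sets in opposite directions. One was the glutathione transferase gene GSTU47, whose probe sets above background on all 5 arrays had log2 differences from -3.45 to 1.17.

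Seed maturation protein genes, of which 15 of 22 were higher in root meristem (camera adjusted p = 0.0011; adjusted p = 0.749 with an estimated correlation), also moved together between the root meristem arrays. The median difference between root meristem arrays 1 and 3 was 1.75 on the log2 scale (random lists of the same size and signal gave values below it in 100% of 10000 draws), with 22 of 22 genes higher on array 1; in non-meristematic tissue only 4 of 22 were above background on both arrays. Tissue of maturing or dry seed is argued against as the whole source. Of 8 storage protein genes, 0 lay above background on at least 2 root meristem arrays, with a highest signal of 21.9. Other transcripts known from seed nevertheless go with seed tissue in direction: BBI-1 and BBI-2 were higher, as were KTI-3 and LEA5 (at least 61.0-fold). The last 2 were among the 4 higher genes of the 6 measured, of 15 seed storage and late embryogenesis genes on the array. The list's median signal fell from 413 to 217 and 122 over root meristem arrays 1 to 3. LEA5 had 2637, 3069 and 852. On their brightest probe sets, BBI-1 (9237, 9735 and 8463), BBI-2 (7390, 8580 and 6807) and KTI-3 (7522, 8700 and 8161) did not follow that fall. KTI-3 also had 1723 and 1137 on non-meristematic arrays 1 and 2. The protease inhibitor genes BBI, KTI1 and KTI3 had no signal above background on any array. A single array as the whole source was tested by asking for a median difference above 1 on every root meristem array. From the non-meristematic mean it was 2.21 in the lowest and 4.01 in the highest, but most non-meristematic signals lay below background. With those signals held at background it was at least 3.15, 2.30 and 1.03 on arrays 1, 2 and 3. The 95% bootstrap interval on array 3 was 0.19 to 2.18, which includes 1. That interval treats genes that move together as independent, so it is too narrow. The list's median was thus higher on every root meristem array, while the size asked for was not secured on array 3. Drying of the tips during dissection may contribute and cannot be told apart from a difference between the tissues: the median log2 difference of 11 dehydration-response genes was 0.17, with a 95% bootstrap interval of -0.53 to 1.04, and their small number keeps it open, as does tissue as an untested explanation.

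The clock gene LHY differed between the 2 non-meristematic arrays more than between the groups. Its 2 probe sets were higher on array 1 by 3.22 and, with array 2 below background, by at least 4.34 on the log2 scale, while the difference between the groups did not pass (adjusted p = 0.664 on the brighter one). The dimmer probe set shares a design cluster number with CAB3 probe sets, so that its assignment is uncertain. General noise between these arrays stays open: the differences lay at the 98.6 and 99.5 percentiles of probe sets of similar signal, but LHY was singled out for its difference, and other genes, such as HS1pro1 (5.09), differed as widely. Different times of day at harvest are a candidate explanation: the LHY-like gene LCL3 was higher on array 1 by at least 2.45, and the evening gene LUXC differed by -2.74 on the probe set above background on both arrays and by -1.06 or further from 0 on the other, which was below background on array 1 (-2.75 on average before such signals were held at background). The labels give no harvest time. Among genes singled out for their spread between the same arrays, ACS1, an ethylene synthesis gene, had 654.6 and 15.4, the latter below background, and AOC4, a jasmonate synthesis gene, 1832 and 99.6 on arrays 1 and 2.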
